A study of Mus musculus with 18 samples.

How the data were processed

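The deposited values are log2 expression summaries, 1 per Affymetrix probe set and array, which the authors made with RMA per the submitters' processing notes; the version of RMA is not given in the sources used here. RMA subtracts background, normalizes the arrays to each other and summarizes the probes of a set. That the values are on a log2 scale was read from their range, which ran from 2.49 to 14.47 over the 18 arrays with array medians between 4.74 and 4.81. The authors' normalization was kept as deposited, and everything below was computed from these values. The correlation of each pair of arrays of the same group lay between 0.987 and 0.995. The 3' minus 5' signal of the actin controls lay between 0.07 and 0.54 and that of the Gapdh controls between -0.31 and 0.03.

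Of 45101 probe sets 34958 carried a single gene symbol in the annotation table of the array, 932 carried several and 9211 were not named there. A table of RefSeq genes (assembly GRCm38.p6) was used only for names and for which genes neighbour each other, and 34754 of the single-symbol probe sets matched it by Entrez number. Each gene was represented by its brightest single-symbol probe set by the mean over all arrays, which gave 18194 genes. Genes were tested when that probe set lay above the 40th percentile of the array on at least 3 arrays; this kept 13679 genes and left 4515 untested. One gene of the fixed set is not reported here.

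Differences were tested with limma 3.58.1 in R 4.3.3. A mean was fitted for each of the 6 groups over all 18 arrays, with 12 residual degrees of freedom, variances were moderated by empirical Bayes, and two-sided p values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. The comparisons were knock-out against wild type within each of the 3 conditions, 1 h and 10 h of TGF-β1 against untreated cells within each genotype, and the difference between the genotypes in the 1 h and the 10 h response. Because the 3 arrays of an embryo are not independent, the genotypes were also compared on the mean of the 3 conditions per embryo, 3 against 3. The untreated arrays serve both TGF-β1 times, so the 1 h and 10 h responses of a genotype share their control arrays and their overlap was not counted. The labels hold no untreated culture kept for 10 h, and cells had stood for hours in medium with an albumin supplement before treatment.

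A set of 26 gene lists was fixed for the NFI family, TGF-β signalling, fibroblast functions, metabolism and markers of other cell types that such cultures could hold. Lists were tested with camera of limma at a preset correlation between genes of 0.01 and again with the correlation estimated for each list, adjusted over the lists. Members were counted over all genes and with p adjusted over the list alone. List means per embryo were compared by an exact permutation test, for which 0.1 is the smallest two-sided p of 3 against 3. The genes named are the 10 with the largest rise and the 10 with the largest fall among those that passed without overlap of the groups, up to 4 members of each list with the smallest adjusted p, a fixed set of genes of the pathway whatever their test, and, where fewer than 5 genes passed, the 5 with the smallest p. The comparisons, the test, the lists, the rule for names and the alternatives not described as added later were chosen before the data were examined.

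Within a genotype the same replicate number marks the same embryo per the labels, so embryo pairs the untreated and treated arrays. The correlation of the deviations from the group means over genes was 0.763, 0.604 and 0.642 between the untreated and 1 h arrays of wild-type embryos 1, 2 and 3 and 0.592, 0.684 and 0.656 for the knock-out embryos. Between the untreated and 10 h arrays it was 0.388, 0.344 and 0.282 for the knock-out embryos and 0.488 for wild-type embryo 1, but -0.06 and -0.20 for wild-type embryos 2 and 3. Wild-type and knock-out embryos with the same number are different embryos; their deviations correlated at 0.346, 0.541 and 0.07 in untreated cells, 0.472, 0.487 and 0.104 at 1 h and 0.135, -0.20 and -0.02 at 10 h. All 3 pairs exceeded 0.1 only at 1 h, number 3 narrowly at 0.104, so the numbers were treated as pairing the genotypes there. This pairing is an assumption that rests on the correlations alone. The same embryos gave all 3 conditions, and nothing in the labels says why a pairing would hold at 1 h only. Results that use it are therefore given as an alternative and decide nothing by themselves. In untreated cells wild-type embryo 1 and knock-out embryo 3, of unlike numbers, correlated at 0.184. With the wild-type 10 h arrays 2 and 3 exchanged, the 10 h values of numbers 2 and 3 would be 0.454 and 0.017.

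The test was tried on simulated arrays of the 13679 genes with known changes of 0.5, 1 and 2 on the log2 scale in 67, 67 and 66 genes. For knock-out against wild type in untreated cells it recovered 35.8%, 88.1% and 95.5% of them with 10 false calls. For the 10 h response of wild type it recovered 40.3%, 91.0% and 97.0% with 5, and for the 10 h interaction 16.4%, 64.2% and 93.9% with 3. For the embryo means the shares were 77.6%, 95.5% and 98.5% with 6 false calls. The simulated arrays were drawn independently, with no effect shared by the arrays of an embryo and no correlation between genes. Arrays of an embryo did vary together in the data, so the shares for the embryo means may be too high.

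Alternatives tried were no filter, a filter at the 60th percentile, the mean of all probe sets of a gene, all probe sets tested singly, centring of each array on its median, quantile normalization, a variance prior with an intensity trend, array weights, a fit on the arrays of the comparison alone, embryo as a fixed or random block, the replicate number as a block between genotypes, and leaving out each embryo in turn. Added after the data were seen were embryo as a fixed block in the list tests, the replicate number as a block in the list test between the genotypes at 1 h, the embryo numbers of the wild-type 10 h arrays 2 and 3 exchanged in the block, the list tests and the embryo means, and both of these arrays left out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.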

Results

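Gene expression was measured on Affymetrix arrays in primary mouse embryonic fibroblasts, connective-tissue cells grown from 14-day embryos after removal of the head and liver. The cells came from 3 wild-type embryos and from 3 embryos labelled as knock-outs of Nfic, the gene of the transcription factor nuclear factor I-C. Cells of each embryo were left untreated or received 12.5 ng/ml of TGF-β1, a growth factor that signals through SMAD proteins, for 1 h to examine the immediate response or for 10 h to examine the delayed one. This gave 6 groups of 3 arrays, 18 arrays in all, and the replicates of a group were separate embryos. The number of arrays limits the precision, and for the median gene the 95% confidence interval of a difference between 2 groups reached 0.27 on the log2 scale to each side. No untreated culture kept for 10 h was analysed here, so every 10 h change compares TGF-β1 and the time in culture together with the untreated cells. Values are log2 fold changes with their standard error from limma, and n is 3 embryos per group.

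Nfic itself was not measurably lower in the cells labelled knock-out. Its brightest probe set read 10.51, 10.36 and 10.49 on the log2 scale in the 3 untreated wild-type cultures and 10.43, 9.89 and 10.72 in the 3 untreated cultures labelled knock-out. After 1 h of TGF-β1 it read 10.77, 10.39 and 10.59 in wild type against 10.65, 10.32 and 10.72. After 10 h it read 10.19, 10.25 and 10.25 against 10.03, 10.23 and 10.17. The difference between the genotypes was -0.10 ± 0.16 in untreated cells, -0.02 ± 0.16 at 1 h and -0.09 ± 0.16 at 10 h (limma adjusted p = 1.00, 0.997 and 0.973). In the mean of the 3 conditions per embryo it was -0.07 ± 0.11 (0.984). The other 4 Nfic probe sets gave the same picture in untreated cells, with means of 6.54 in wild type and 6.13 in labelled knock-out, 5.11 and 5.04, 6.66 and 6.31, and 6.46 and 6.50. Over all 18 arrays these probe sets ranged from 5.63 to 6.96, from 4.74 to 5.68, from 5.64 to 6.94 and from 6.19 to 6.95. For each probe set the values of the 2 genotypes overlapped in untreated cells. The labels do not say which part of Nfic was deleted and the positions of the probes were not used here. A probe set outside the deleted part could read the same in both genotypes, so these values do not decide whether the labels hold. The genotype is therefore given below as labelled.

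**Figure D1:**
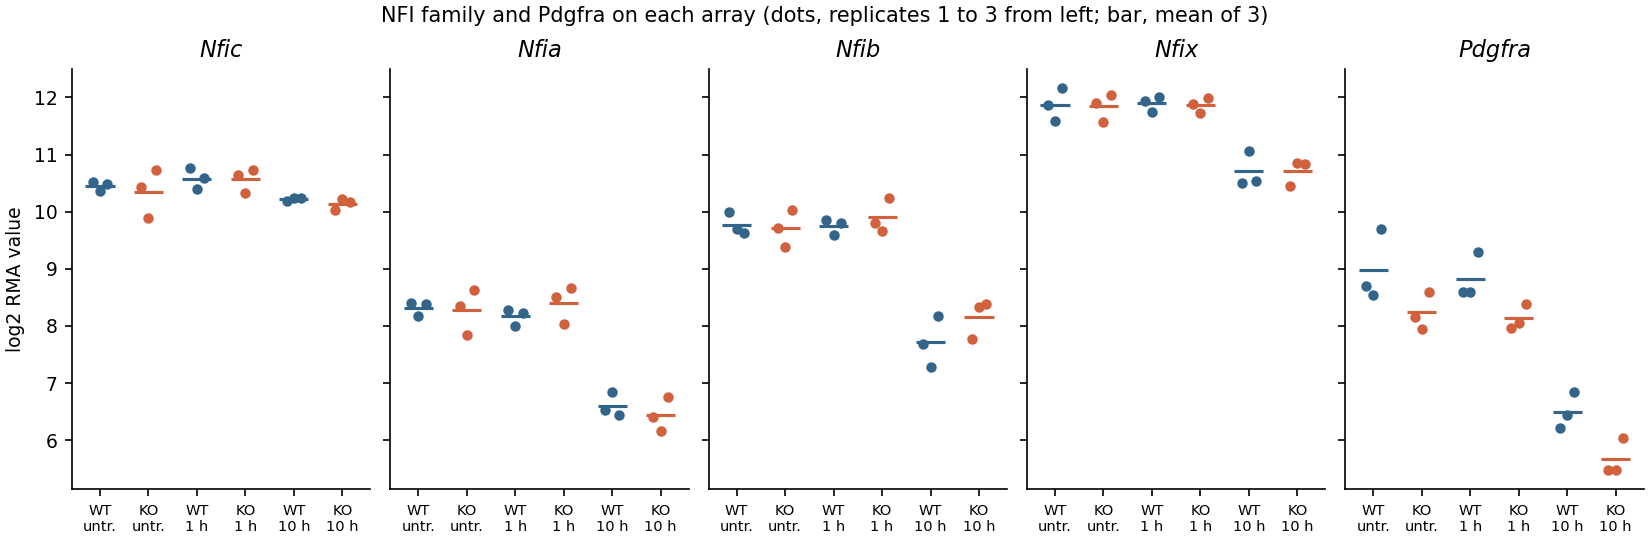
Log2 RMA values of Nfic, Nfia, Nfib, Nfix and Pdgfra (brightest probe set of each) on each of the 18 arrays, with dots for the 3 replicates of a group in the order 1 to 3 and a bar for their mean. Nfic lay between 9.89 and 10.77 on all arrays, whereas Nfia, Nfib, Nfix and Pdgfra were lower in the 10 h groups of both genotypes.

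In untreated cells no gene passed the test between the genotypes. The smallest p belonged to Kcnmb4, a regulatory subunit of calcium-activated potassium channels, at 0.65 ± 0.12 (limma adjusted p = 0.746). It was followed by Plscr2 at 0.73 ± 0.15, Prrt1 at 0.48 ± 0.10, Angpt4 at 0.53 ± 0.12 and Tcn2, a vitamin B12 carrier, at 0.42 ± 0.09, each with an adjusted p of 0.961. Of 13679 tested genes 0 passed in limma and 460 had an unadjusted p under 0.05, where 684 would by chance. In 7.93% of genes the 3 values of one genotype all lay above the 3 of the other, where chance gives 10%. The 95% interval of the difference lay within 2-fold in either direction for 96.7% of the genes. The platelet-derived growth factor receptor Pdgfra was -0.74 ± 0.29, its ligand gene Pdgfa -0.10 ± 0.16, Tgfb1 -0.10 ± 0.19, the SMAD-induced feedback inhibitor Smad7 0.10 ± 0.10, Ccn2 0.16 ± 0.13 (adjusted p = 1.00 each). Acta2 was 0.01 ± 0.07, Col1a1 -0.06 ± 0.11 and the cell cycle inhibitor Cdkn1a 0.09 ± 0.09 (1.00 each). The probe sets read for Acta2 and Col1a1 lay between 13.89 and 14.18 and between 13.61 and 14.03 on all arrays, near the highest value on any array (14.47), so folds near 0 there do not exclude a change, here and below. Among the family members, Nfia was -0.05 ± 0.20, Nfib -0.06 ± 0.23 and Nfix -0.03 ± 0.17 (adjusted p = 1.00 each).

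Among the 26 gene lists, the sterol synthesis genes stood lower in untreated cells labelled knock-out, with a median of -0.41 over 17 genes (camera adjusted p = 3.8e-14, adjusted p = 0.245 with an estimated correlation). The 19 macrophage and haematopoietic markers had a median of -0.59 (adjusted p = 4.7e-04, adjusted p = 0.518 with an estimated correlation). Lyz2 was at -0.33 ± 0.56 and Csf1r at -0.57 ± 0.70, members named after their values were seen. The 23 interferon response genes had a median of -0.21 (0.0169 and 0.709 as adjusted p without and with an estimated correlation). A higher position was called for the osteogenic and chondrogenic genes (0.0169 and 0.245), the Hox genes (0.0103 and 0.245), the epithelial and keratinocyte markers (0.0044 and 0.312) and the neural, glial and neural crest markers (0.0169 and 0.245). Their medians were 0.10, 0.15, 0.13 and 0.12. In these lists 0 members passed in limma over all genes. Adjusted over the list alone 1 epithelial marker passed and 0 members of the other 6 lists did. Of the 7 lists only sterol synthesis kept its call without each embryo in turn. The macrophage markers lost theirs without wild-type embryo 1 (adjusted p = 0.579) or knock-out embryo 2 (0.119). Without wild-type embryo 1 the other 5 lists lost theirs too, the interferon response (0.773), the osteogenic genes (0.263), the Hox genes (0.263), the epithelial markers (0.183) and the neural markers (0.183). Without knock-out embryo 2 so did the interferon response (0.118), the osteogenic genes (0.107), the Hox genes (0.315), the epithelial markers (0.0728) and the neural markers (0.0625). The interferon response was also lost without wild-type embryo 3 (0.252) or knock-out embryo 3 (0.177), the osteogenic genes without wild-type embryo 2 (0.0735) and the neural markers without wild-type embryo 3 (0.169). On the level of embryos, the mean of the sterol list was 8.86, 9.48 and 9.13 in the 3 wild-type cultures and 8.61, 8.97 and 8.61 in the 3 labelled knock-out (two-sided exact permutation p = 0.2, where 0.1 is the smallest possible). That of the macrophage list was 9.97, 8.56 and 8.51 against 9.35, 7.79 and 8.23 (exact permutation p = 0.5).

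TGF-β1 for 1 h raised a small set of early genes in wild-type cells. The largest rises were those of Rasl11b, a small GTPase gene, at 3.25 ± 0.19, or 9.54-fold (limma adjusted p = 1.0e-07), and of the zinc finger factor gene Egr2 at 2.54 ± 0.17. Next came Ier3 at 2.36 ± 0.32, Id1, an inhibitor of basic helix-loop-helix factors, at 2.36 ± 0.22, and the cytokine gene Lif at 2.25 ± 0.35. They were followed by Snai1, a repressor of epithelial genes, at 2.22 ± 0.17, the growth factor gene Hbegf at 2.09 ± 0.13, the TGF-β-inducible factor gene Klf10 at 2.09 ± 0.14, Bhlhe40 at 2.02 ± 0.29 and Id2 at 1.92 ± 0.36. Fewer genes fell, led by Ppp1r3c, a glycogen-targeting subunit of protein phosphatase 1, at -1.75 ± 0.21, with Zfp53 at -0.87 ± 0.12, 9930012K11Rik at -0.81 ± 0.11 and Cited2 at -0.77 ± 0.12. In all 80 genes passed, of which 69 were higher and 11 lower. By at least 2-fold 37 rose and 2 fell, and 940 had an unadjusted p under 0.05 (1282 with embryo as a fixed block).

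The SMAD feedback and early TGF-β targets moved as a group at 1 h in wild-type cells. Of 19 tested members 9 rose, 0 fell and 10 did not pass, and adjusted over the list alone 16 rose. Smad7 rose by 1.88 ± 0.10, or 3.68-fold (adjusted p = 6.5e-08), Skil, a repressor of SMAD activity, by 1.16 ± 0.14 and the matricellular protein gene Ccn2 by 1.05 ± 0.13. This list passed camera (adjusted p = 5.2e-37) and also with an estimated correlation (adjusted p = 1.2e-05), the only one of the 26 to do so. Of 29 immediate early genes 4 rose (Egr2, Ier3, Ccn1 at 1.06 ± 0.16 and Nr4a1 at 1.67 ± 0.33). In this list 12 rose and 1 fell adjusted over the list alone (camera adjusted p = 6.4e-10, adjusted p = 0.181 with an estimated correlation). Of 32 secreted growth factors and binding proteins 5 rose, among them Hbegf, Wnt9a at 1.60 ± 0.17, Fgf21 at 1.00 ± 0.15 and Fgf18 at 1.42 ± 0.22. The list had 6 rises adjusted over the list alone (2.4e-04 and 0.181 as adjusted p without and with an estimated correlation). Of 24 chemokine and inflammation genes 2 rose, Lif and the prostaglandin synthase gene Ptgs2 at 1.31 ± 0.18, and 3 adjusted over the list alone (0.0021 and 0.732). Of 18 osteogenic and chondrogenic genes the tendon factor gene Scx rose by 0.98 ± 0.21, and 2 adjusted over the list alone (0.0059 and 0.181). The interferon response list lay lower with a median of -0.23 and the epithelial list higher with a median of 0.12, both with 0 members past limma and 0 adjusted over the list alone (0.0078 and 0.888, and 0.0447 and 0.705). With embryo as a fixed block in the list test, the epithelial list was no longer called (adjusted p = 0.0832) and the PDGF pathway list was (0.0340, against 0.0843 without the block). Gadd45b, which is induced by stress and TGF-β, rose by 1.92 ± 0.22 as 1 of 17 CDK inhibitors and p53 targets. Pdgfa at 0.26 ± 0.16, Pdgfra at -0.15 ± 0.29, Tgfb1 at 0.25 ± 0.19, Acta2 at 0.03 ± 0.07, Col1a1 at -0.01 ± 0.11 and Cdkn1a at 0.05 ± 0.09 did not pass. A dimmer Acta2 probe set was at 0.89 ± 0.29 in wild type and 1.15 ± 0.29 in labelled knock-out (limma adjusted p = 0.550 and 0.247 over all probe sets). Also short of the threshold were Nfic at 0.13 ± 0.16, Nfia at -0.15 ± 0.20, Nfib at -0.03 ± 0.23 and Nfix at 0.02 ± 0.17. With 1 wild-type embryo left out 41, 48 and 38 genes passed (without embryo 1, 2 and 3). Of 31 named genes past the threshold 18 passed without each of the 6 embryos in turn. Lif, Bhlhe40, Id2, Cited2, Nr4a1, Fgf21 and Scx were among the 13 that did not. Without wild-type embryo 1 the interferon response, osteogenic and epithelial lists lost their calls (adjusted p = 0.224, 0.0695 and 0.225).

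**Figure D2:**
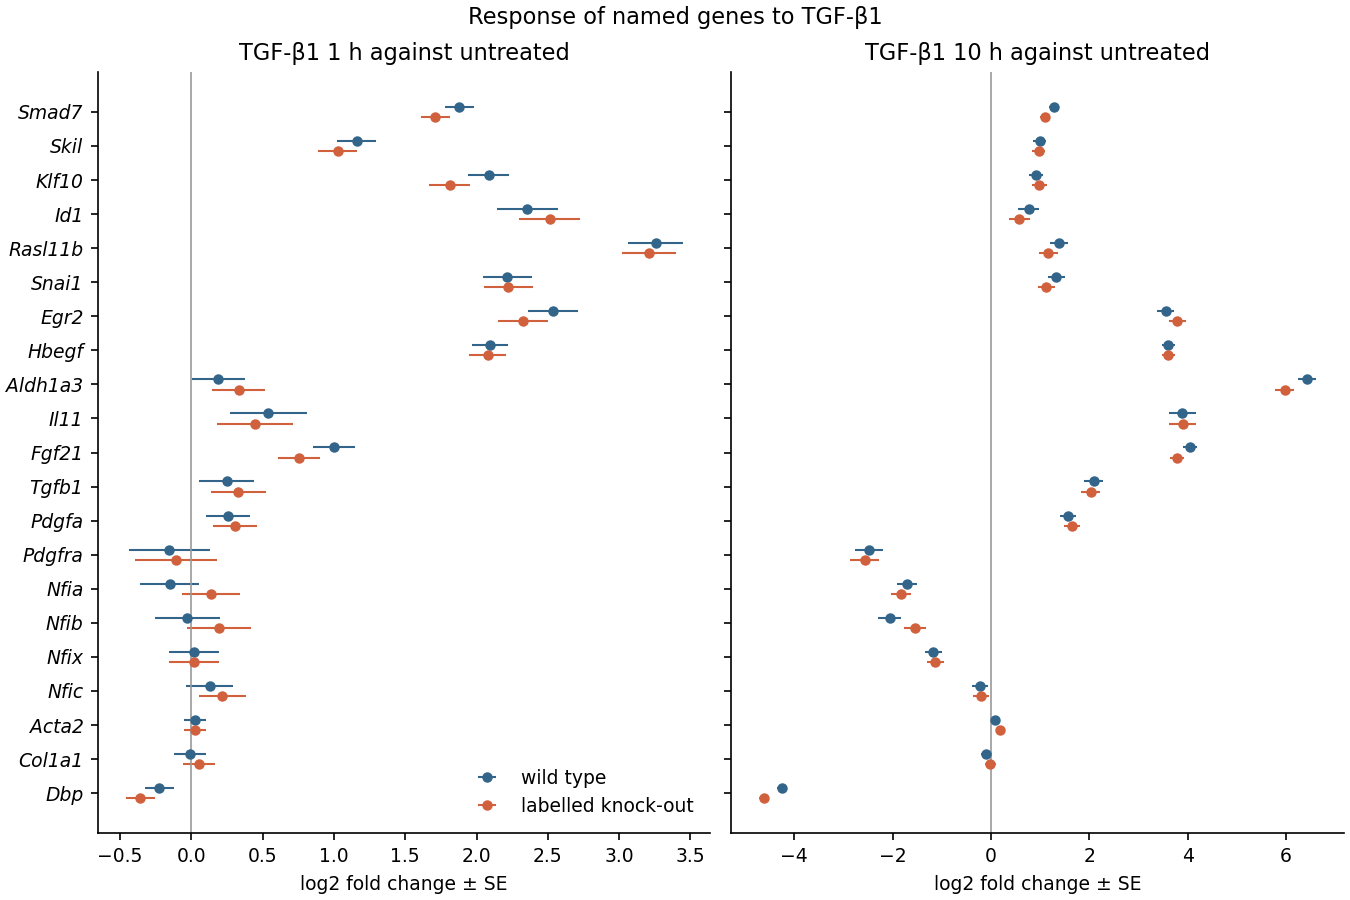
Log2 fold change against untreated cells (points) with its standard error (bars) for 21 named genes after 1 h (left) and 10 h (right) of TGF-β1, in wild-type cells and cells labelled knock-out, n = 3 embryos per group; the horizontal axes differ. Smad7 rose by 1.88 at 1 h and by 1.28 at 10 h in wild type, and Aldh1a3 by 6.42 at 10 h.

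Cells labelled knock-out also raised a small set of early genes after 1 h of TGF-β1. Rasl11b rose by 3.21 ± 0.19 (limma adjusted p = 1.3e-07), Id1 by 2.51 ± 0.22, Egr2 by 2.33 ± 0.17, Snai1 by 2.22 ± 0.17 and Hbegf by 2.08 ± 0.13. Gadd45b rose by 1.90 ± 0.22, Bhlhe40 by 1.90 ± 0.29, Lif by 1.89 ± 0.35, Klf10 by 1.81 ± 0.14 and the Notch target gene Hes1 by 1.81 ± 0.19. The largest falls were those of Ppp1r3c at -1.36 ± 0.21, 9930012K11Rik at -1.01 ± 0.11, Cited2 at -0.89 ± 0.12, Tent5a at -0.87 ± 0.17 and Zfp53 at -0.85 ± 0.12. In all 67 genes passed, 57 higher and 10 lower. By at least 2-fold 29 rose and 2 fell, and 512 had an unadjusted p under 0.05 (697 with embryo as a fixed block). Of the SMAD feedback and early TGF-β targets 8 of 19 rose and 0 fell, and 14 rose adjusted over the list alone. Smad7 was at 1.71 ± 0.10, Skil at 1.03 ± 0.14 and Ccn2 at 0.84 ± 0.13 (camera adjusted p = 4.2e-51, adjusted p = 2.0e-06 with an estimated correlation). Of 29 immediate early genes 4 rose and 9 adjusted over the list alone, with Ier3 at 1.78 ± 0.32 and Rhob at 0.61 ± 0.12 (1.7e-14, and 0.0849 with an estimated correlation). Of 32 secreted growth factors 5 rose and 6 adjusted over the list alone, with Wnt9a at 1.47 ± 0.17, Fgf18 at 1.74 ± 0.22 and Vegfa at 0.76 ± 0.15 (7.5e-07 and 0.0849). Lif and Ptgs2, at 1.10 ± 0.18, were again the 2 of 24 chemokine and inflammation genes that rose, and 2 did adjusted over the list alone. The list was called higher (0.0354 and 0.714) with a mean of 0.14 but a median of -0.02. The osteogenic and chondrogenic list was called higher with 0 members past limma and 3 adjusted over the list alone (0.0015 and 0.0849). So was the PDGF pathway list with 0 and 0 (0.0481 and 0.320). With embryo as a fixed block 101 genes passed, which included 66 of the 67. The Hox list was then called higher in the list test (adjusted p = 0.0349, against 0.0701 without the block). Without knock-out embryo 1, 2 or 3 the counts were 36, 29 and 26. Of 30 named genes past the threshold 14 passed without each of the 6 embryos in turn. Bhlhe40, Lif, Ppp1r3c, Cited2, Tent5a, Ier3, Rhob, Vegfa, Ptgs2 and Ccn2 were among the 16 that did not. The chemokine list lost its call without knock-out embryo 2 or 3 (adjusted p = 0.117 and 0.161), and so did the PDGF pathway list (0.123 and 0.151). The PDGF pathway list also lost its call without wild-type embryo 1, 2 or 3 (camera adjusted p = 0.0612, 0.0598 and 0.0596).

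A difference between the genotypes in the 1 h response was not detectable for any gene. Of the 13679 genes 0 passed the interaction test in limma and 233 had an unadjusted p under 0.05, and with embryo as a fixed block, which takes up the pairing of the arrays, 0 and 359. The interval of the difference lay within 2-fold for 93.7% of the genes. The smallest p belonged to Epor at -0.63 ± 0.14, Trav9d-3 at -0.50 ± 0.11, Lalba at -0.57 ± 0.14, Lcn8 at -0.53 ± 0.14 and Siglech at -0.53 ± 0.15, each with an adjusted p of 1.00. Smad7 differed by -0.17 ± 0.14, Ccn2 by -0.20 ± 0.19 and Pdgfa by 0.05 ± 0.22 (adjusted p = 1.00 each). Of the genes called in wild type and in labelled knock-out 54 were shared, 47 higher and 7 lower in both, where independent lists would share 0.296 in the same direction. In labelled knock-out 79 of the 80 genes called in wild type had the same sign. Across all tested genes the 2 responses, which share no array, correlated with a Pearson r of 0.586 and a Spearman rho of 0.261. Across the 80 genes called in wild type the r was 0.972. Genes are not independent replicates. No list passed camera for the interaction (smallest adjusted p = 0.0833). With embryo as a fixed block the interferon response list (0.0173), the matrix glycoprotein list (0.0257) and the 4 tested sex-linked genes (0.0173) did, and 0 did with an estimated correlation.

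By 10 h of TGF-β1 a large part of the transcriptome had changed in wild-type cells. Aldh1a3, an enzyme of retinoic acid synthesis, rose by 6.42 ± 0.19, or 85.8-fold (limma adjusted p = 2.8e-12). The gap junction gene Gjb2 rose by 4.05 ± 0.27, the hormone gene Fgf21 by 4.05 ± 0.15, the cytokine gene Il11 by 3.90 ± 0.27 and the natriuretic peptide gene Nppb by 3.66 ± 0.31. Lce1f rose by 3.63 ± 0.17, Hbegf by 3.61 ± 0.13, Egr2 by 3.56 ± 0.17, Il6 by 3.36 ± 0.52 and the scavenger receptor gene Olr1 by 3.35 ± 0.34. The largest falls were those of Dbp, a clock-controlled transcription factor, at -4.25 ± 0.10 (2.9e-13), the Wnt agonist gene Rspo2 at -4.18 ± 0.31, the lipase gene Lpl at -3.56 ± 0.56, the iron exporter gene Slc40a1 at -3.48 ± 0.19 and the aggrecanase gene Adamts5 at -3.24 ± 0.14. They were followed by Rtl3 at -3.17 ± 0.38, Lrrn3 at -3.13 ± 0.27, Ptx3 at -3.02 ± 0.76, Gas1 at -2.93 ± 0.32 and Fbxl7 at -2.92 ± 0.17. A second Rspo2 probe set passed in the opposite direction in wild type. Of 13679 genes 4614 passed (33.7%), 2041 higher and 2573 lower. Of these 310 rose and 523 fell by at least 2-fold.

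Of the NFI family, 3 of the 4 members fell, Nfic being the exception. In wild type Nfia fell by 1.71 ± 0.20, Nfib by 2.06 ± 0.23 and Nfix by 1.17 ± 0.17, whereas Nfic was -0.22 ± 0.16 (limma adjusted p = 1.3e-05, 5.7e-06, 1.0e-04 and 0.314; camera adjusted p = 0.0052, adjusted p = 0.340 with an estimated correlation). The family had 3 members lower adjusted over the list alone as well. Within the PDGF pathway 3 ligand genes rose and the receptor gene fell. Pdgfa rose by 1.57 ± 0.16, Pdgfb by 1.79 ± 0.51 and Pdgfc by 1.37 ± 0.11. Pdgfra fell by 2.48 ± 0.29 and the ligand gene Pdgfd, named after its value was seen, by 0.52 ± 0.17, so that 3 of 7 members were higher and 2 lower, and 5 and 2 adjusted over the list alone (camera adjusted p = 0.188). Of the SMAD feedback and early TGF-β targets 11 of 19 rose and 3 fell, and 12 and 3 did adjusted over the list alone. Smad7 rose by 1.28 ± 0.10, Ldlrad4 by 1.05 ± 0.09, the ubiquitin ligase gene Smurf1 by 1.27 ± 0.11 and Ccn2 by 1.53 ± 0.13 (5.0e-04, and 0.305 with an estimated correlation). The Ccn2 probe set read 13.76 to 14.13 at 10 h in wild type and 13.95 to 14.05 in labelled knock-out, near the highest array values, so its 10 h folds are not exact and do not exclude a larger rise. Among TGF-β superfamily ligands, receptors and SMADs 8 of 32 rose, as Inhba at 2.79 ± 0.12 and Tgfb1 itself at 2.09 ± 0.19 did. Another 4 fell, as Smad3 at -0.88 ± 0.09 and the co-receptor gene Tgfbr3 at -2.85 ± 0.32 did, with the same counts adjusted over the list alone (camera adjusted p = 0.415). The immediate early genes were still higher, with 15 of 29 up and 1 down, or 18 and 1 adjusted over the list alone. Dusp5 rose by 2.56 ± 0.15, Fosl1 by 1.83 ± 0.17 and Maff by 1.73 ± 0.21 (3.5e-08, and 0.340 with an estimated correlation).

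Structural genes of the fibroblast moved unevenly in wild type. Of 20 contractile and myofibroblast genes 8 rose and 0 fell, over all genes and adjusted over the list alone. The integrin gene Itga5 rose by 2.70 ± 0.14, Smtn by 1.04 ± 0.16, Cnn1 by 1.38 ± 0.25 and Tagln by 0.48 ± 0.07 (camera adjusted p = 4.8e-05, adjusted p = 0.340 with an estimated correlation), where Tagln, at a mean of 13.87, was near the highest array values too. The smooth muscle actin gene Acta2 was 0.08 ± 0.07 (adjusted p = 0.459) in its probe set near the highest array values, and 0.50 ± 0.44 and 0.39 ± 0.29 in its 2 dimmer ones (neither passed over all probe sets). Of 21 collagens 5 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.278). Col8a2 rose by 2.65 ± 0.39 and Col5a3 by 1.22 ± 0.25, and Col11a1 fell by 0.48 ± 0.10. Col1a1 was -0.09 ± 0.11 (0.540) in its probe set near the highest array values and 0.99 ± 0.35 in the other (limma adjusted p = 0.0674 over all probe sets), so its change stays undecided. Among 36 matrix glycoproteins, proteoglycans and crosslinkers 7 rose, as the hyaluronan synthase gene Has2 at 3.13 ± 0.23 and Tnc at 1.31 ± 0.10 did. Another 5 fell, as Ogn at -1.43 ± 0.22 and Nid1 at -0.63 ± 0.12 did, also over the list alone (0.374). Of 24 matrix proteases and inhibitors 9 rose and 6 fell, or 10 and 7 adjusted over the list alone. Plaur was at 1.94 ± 0.16 and Adam12 at 1.81 ± 0.15 against Adamts1 at -2.64 ± 0.21 (0.617; median 0.00, mean -0.02). Secreted growth factors rose in 11 and fell in 8 of 32 members, 11 and 10 adjusted over the list alone, with Vegfa at 2.54 ± 0.15 and Fgf2 at 2.94 ± 0.30 among the rises (0.237). The osteogenic and chondrogenic list had 7 rises and 1 fall among 18, 8 and 1 adjusted over the list alone, with Scx at 1.03 ± 0.21 and Msx1 at 0.49 ± 0.12 (0.0581, and 0.0330 with the labelled embryo number as a fixed block). The adipogenic list had 1 rise and 4 falls among 15, also over the list alone, with Lpl and the adipocyte master regulator gene Pparg, at -0.80 ± 0.21, among the falls (0.597).

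Proliferation genes fell without exception among those that passed. Of 29 cell cycle genes 21 fell, 0 rose and 8 did not pass, and 26 fell adjusted over the list alone. Mcm7 was at -0.83 ± 0.11, Mki67 at -1.38 ± 0.21, Rrm1 at -0.72 ± 0.12 and Bub1 at -1.37 ± 0.23. The median was -0.63 (camera adjusted p = 4.0e-08, adjusted p = 0.427 with an estimated correlation). The CDK inhibitors and p53 targets split into 5 higher and 5 lower of 17, 6 and 5 adjusted over the list alone. Among them were Gadd45a at 1.12 ± 0.20 against Trp53inp1 at -1.20 ± 0.14 and Sesn1 at -1.39 ± 0.23 (0.879; median 0.09, mean -0.02). Cdkn1a was 0.23 ± 0.09 (adjusted p = 0.0641), but its dimmer probe set passed at 0.46 ± 0.14 (limma adjusted p = 0.0289 over all probe sets). Of 23 interferon response genes 11 fell and 0 rose, and 12 fell adjusted over the list alone. Ifit2 was at -2.46 ± 0.21, Ifit3 at -2.53 ± 0.44 and Tap1 at -0.78 ± 0.15 (camera adjusted p = 0.0018, adjusted p = 0.578 with an estimated correlation). The chemokine and inflammation genes went both ways, 7 up and 5 down of 24, also over the list alone, with Ptgs2 at 2.55 ± 0.18 and Lif at 2.66 ± 0.35 beside Il11 and Il6 among the rises (0.194). Of 27 Hox genes, which mark position along the body axis, 9 fell and 1 rose, also over the list alone. Hoxa7 was at -1.10 ± 0.15 and Hoxc8 at -1.14 ± 0.16 against Hoxb2 at 1.21 ± 0.16 (0.0916, and 0.01 with the labelled embryo number as a fixed block). Of 24 glycolysis and hypoxia genes 6 rose, as the glucose transporter gene Slc2a1 at 1.51 ± 0.18 and Hk2 at 1.52 ± 0.23 did, while 2 fell, also over the list alone (0.420). Of 17 sterol synthesis genes 0 passed over all genes or over the list alone (0.788).

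Among the markers of other cell types only the epithelial list passed camera in wild type with all embryos and without a block. Of 18 epithelial and keratinocyte markers 6 rose and 1 fell, also over the list alone, with the desmosomal gene Pkp1 at 2.47 ± 0.22 and Sfn at 2.21 ± 0.31 (camera adjusted p = 0.0144, adjusted p = 0.461 with an estimated correlation, and 0.0635 without wild-type embryo 2). Of 11 skeletal muscle markers 4 rose, as Acta1 at 2.07 ± 0.29 did, also over the list alone (0.0759, and 0.0387 with the labelled embryo number as a fixed block). Of 12 endothelial markers Flt1 rose by 1.69 ± 0.16 (0.0806, and 0.0404 without wild-type embryo 3). Of 14 neural, glial and neural crest markers 2 rose and 2 fell, with Nes at 1.79 ± 0.11 and Map2 at -1.82 ± 0.29 (0.276). Of 4 sex-linked genes Kdm6a fell by 0.44 ± 0.14 (0.408), with the same counts over each list alone. Of 19 macrophage and haematopoietic markers Kit was higher at 0.32 ± 0.09 and Mrc1 lower at -2.15 ± 0.79, 0 passed over the list alone (0.788). Of 5 hepatocyte markers 0 passed over all genes or the list alone (0.276). Leaving out the wild-type 10 h arrays 2 and 3, which correlated poorly with the earlier arrays of the same embryo numbers, gave 2516 genes in wild type, an alternative added after the data were seen that left 1 wild-type 10 h array, whose spread is assumed to be that of the other groups. With the embryo numbers of these 2 arrays exchanged in the block, the osteogenic (0.0358), Hox (0.0104) and muscle lists (0.0283) were called as well. Of the 2516 genes, 2324 were among the 4614. Of 100 named genes past the threshold in wild type 82 passed without each of the 6 embryos in turn. Among those that did not were Pdgfb, Ptx3, Pparg, Mrc1, Kit and Kdm6a.

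In cells labelled knock-out a large part of the transcriptome had changed by 10 h too. Aldh1a3 rose by 5.97 ± 0.19 (limma adjusted p = 8.6e-12), Gjb2 by 4.34 ± 0.27, Olr1 by 4.17 ± 0.34, Il11 by 3.90 ± 0.27, and Egr2 by 3.79 ± 0.17. Fgf21 rose by 3.78 ± 0.15, Il6 by 3.71 ± 0.52, Nppb by 3.65 ± 0.31, the protease inhibitor gene Tfpi2 by 3.63 ± 0.28 and Hbegf by 3.61 ± 0.13. The largest falls were those of Dbp at -4.61 ± 0.10, Rspo2 at -3.99 ± 0.31, Ppp1r3c at -3.78 ± 0.21, Slc40a1 at -3.36 ± 0.19 and Rtl3 at -3.23 ± 0.38. Lpl followed at -3.21 ± 0.56, Adamts5 at -2.90 ± 0.14, Fbxl7 at -2.83 ± 0.17, Tgfbr3 at -2.77 ± 0.32 and Serpinb6b at -2.72 ± 0.35. In all 4745 genes passed (34.7%), 1908 higher and 2837 lower. Of these 359 rose and 515 fell by at least 2-fold. Nfia fell by 1.83 ± 0.20, Nfib by 1.55 ± 0.23 and Nfix by 1.13 ± 0.17, and Nfic was -0.21 ± 0.16 (adjusted p = 0.369). The family, with 3 lower also over the list alone, passed camera (adjusted p = 0.0144, adjusted p = 0.366 with an estimated correlation). Pdgfa rose by 1.65 ± 0.16, Pdgfb by 2.54 ± 0.51 and Pdgfc by 1.36 ± 0.11, and Pdgfra fell by 2.57 ± 0.29, which made 4 of 7 PDGF pathway genes higher and 2 lower, also over the list alone (0.0979). Tgfb1 rose by 2.03 ± 0.19 and Inhba by 2.81 ± 0.12, and Smad3 fell by 1.06 ± 0.09. In all 9 of the 32 superfamily genes rose and 5 fell, 10 and 5 adjusted over the list alone (0.329; median -0.06, mean 0.09).

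Of the 7 lists that passed camera at 10 h in wild type 6 passed in labelled knock-out as well, and the interferon response did not with all embryos and the filter. Of the SMAD feedback and early targets 12 of 19 rose and 4 fell, 12 and 5 adjusted over the list alone, with Smad7 at 1.11 ± 0.10 and Ccn2 at 1.44 ± 0.13 (camera adjusted p = 9.97e-04, adjusted p = 0.308 with an estimated correlation). Of 29 immediate early genes 20 rose and 0 fell, also over the list alone (3.3e-10 and 0.308). Of 20 contractile genes 11 rose and 0 fell, 13 adjusted over the list alone, with Itga5 at 2.86 ± 0.14 and Vcl at 0.53 ± 0.09 (1.4e-06 and 0.308). Of 29 cell cycle genes 25 fell and 0 rose, 27 adjusted over the list alone, with Mcm7 at -1.11 ± 0.11, Rrm2 at -0.86 ± 0.13 and Ccna2 at -0.99 ± 0.16 (6.5e-09 and 0.366). Acta2 was 0.18 ± 0.07 (adjusted p = 0.0764), Col1a1 -0.01 ± 0.11 (0.954) and Cdkn1a 0.22 ± 0.09 (0.0768). Of the dimmer Acta2 probe sets 1 passed at 0.89 ± 0.29 (limma adjusted p = 0.0455 over all probe sets) and the other was 1.31 ± 0.44 (0.0541), while the dimmer one of Col1a1 was 0.88 ± 0.35 (0.106) and that of Cdkn1a 0.30 ± 0.14 (0.172). Of 24 chemokine and inflammation genes 9 rose and 3 fell, 10 and 4 adjusted over the list alone, with Ptgs2 at 2.97 ± 0.18, Lif at 3.23 ± 0.35 and Csf1 at 1.74 ± 0.23 (0.0015 and 0.433). Of 23 interferon response genes 5 fell and 0 rose, also over the list alone, with Ifit2 at -2.05 ± 0.21 (0.0979, but called lower without knock-out embryo 1 at 6.1e-04 and without the filter at 0.0473). The secreted growth factors had 11 rises and 5 falls among 32, 11 and 8 adjusted over the list alone (0.0299, 0.371 with an estimated correlation, and 0.0619 with embryo as a fixed block). The Hox genes had 1 rise and 11 falls among 27, also over the list alone (0.0299 and 0.366). Epithelial markers rose in 6 and fell in 0 of 18, also over the list alone, with Pkp1 at 2.27 ± 0.22 (0.0209 and 0.382, and 0.0513 without knock-out embryo 3). Among lists that did not pass camera, 5 of 21 collagens rose and 2 fell (0.250), 9 of 36 matrix glycoproteins rose and 2 fell (0.159). In the same way 3 of 18 osteogenic genes rose and 1 fell (0.117), 1 of 15 adipogenic genes rose and 3 fell (0.597), and 5 of 24 glycolysis genes rose and 2 fell (0.386), with the same counts over each list alone. Of 24 matrix proteases and inhibitors 7 rose and 6 fell, 11 and 6 adjusted over the list alone (0.186). Of 17 CDK inhibitors and p53 targets 4 rose and 4 fell, 5 and 4 adjusted over the list alone (0.937, called in neither direction, with a median of -0.08). Acta1 rose by 1.98 ± 0.29 as 1 of 11 muscle markers (0.186), Nes by 1.87 ± 0.11 while Map2 fell by 1.08 ± 0.29 among 14 neural markers (0.691), both also over the list alone. Of 12 endothelial markers 2 passed, with Flt1 at 2.00 ± 0.16, and 1 passed adjusted over the list alone (0.0974). Pmvk of the sterol list fell by 0.40 ± 0.13 (0.937) and Kdm6a of the sex-linked list by 0.40 ± 0.14 (0.937), with 0 adjusted over each list alone. Of the macrophage (0.833) and hepatocyte markers (0.937) 0 passed, over all genes or over the list alone. Of 96 named genes past the threshold 81 passed without each of the 6 embryos in turn.

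**Figure D3:**
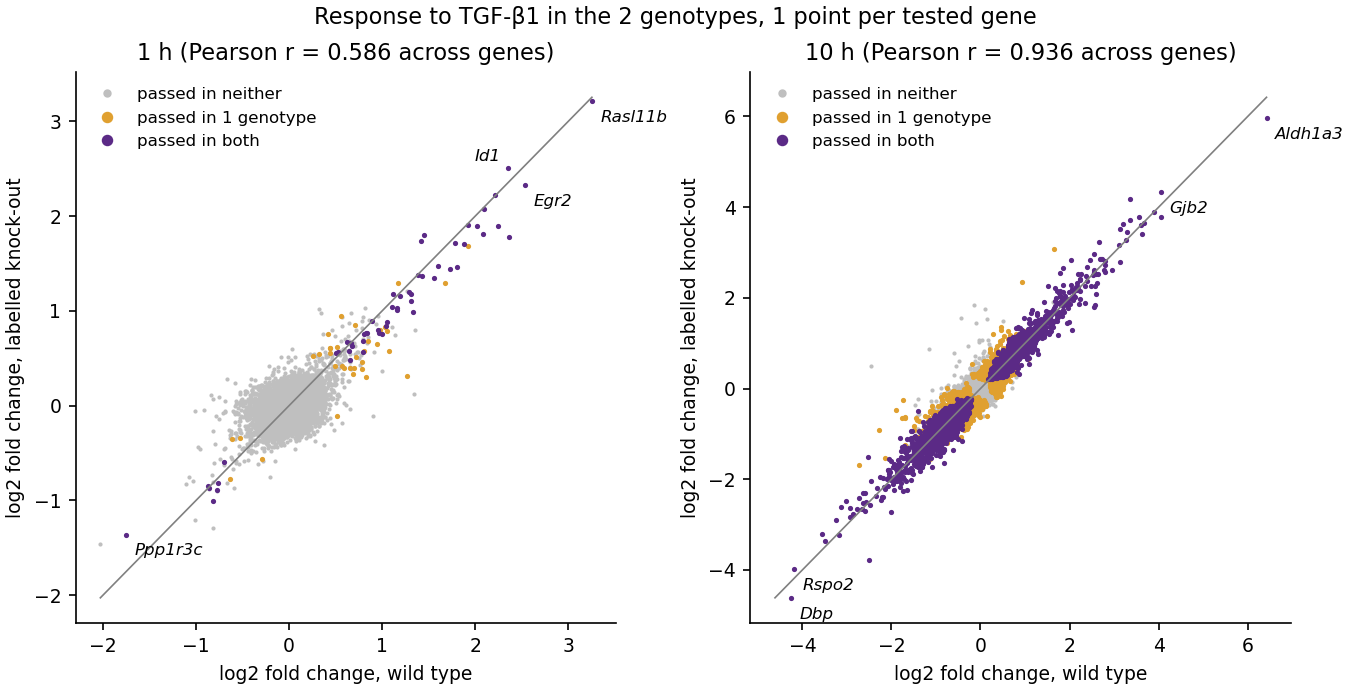
Log2 fold change after 1 h (left) and 10 h (right) of TGF-β1 in cells labelled knock-out (vertical) against wild-type cells (horizontal), with 1 point per tested gene, coloured by whether it passed in both genotypes, in 1 or in neither, and a line of equal change. The Pearson r across genes was 0.586 at 1 h and 0.936 at 10 h.

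No gene was shown to respond differently to 10 h of TGF-β1 in the 2 genotypes. In limma 0 genes passed the interaction test and 305 had an unadjusted p under 0.05, and with embryo as a fixed block 0 and 485 (0 and 633 with the numbers of the wild-type 10 h arrays 2 and 3 exchanged). The interval of the difference lay within 2-fold for 92.9% of genes. The smallest p belonged to Timeless at -0.74 ± 0.17, Myl10 at 0.53 ± 0.12, Ppp1r3c at -1.27 ± 0.30, 2410018L13Rik at -0.57 ± 0.15 and Kcnmb4 at -0.62 ± 0.17, each with an adjusted p of 0.999. The fall of Nfib differed by 0.51 ± 0.32 between the genotypes, that of Pdgfra by -0.09 ± 0.41 and the rise of Pdgfa by 0.09 ± 0.22 (0.999 each). Of the called genes 3690 were shared, 1504 higher and 2186 lower in both, where independent lists would share 818 in the same direction. In labelled knock-out 4562 of the 4614 genes called in wild type had the same sign. The 2 responses correlated across genes with a Pearson r of 0.936, a Spearman rho of 0.889 and a slope of 1.01. Of the lists, the chemokine and inflammation genes (median 0.58, camera adjusted p = 6.9e-06, adjusted p = 0.725 with an estimated correlation), the interferon response genes (0.37, 2.4e-04 and 0.737) and the matrix proteases and inhibitors (0.18, 0.0098 and 0.0929) were called higher in the interaction, with 0 members past limma or adjusted over the list alone. With embryo as a fixed block in the list test the immediate early genes (0.0490) and the secreted growth factors (0.0146) were called too, and also with the numbers of the wild-type 10 h arrays 2 and 3 exchanged (0.0413 and 0.0200). Without knock-out embryo 1 or wild-type embryo 3 the count was 0 lists, without wild-type embryo 2 it was 6 and without knock-out embryo 2 it was 5. The macrophage and haematopoietic markers had a median interaction of 0.13, with Lyz2 at 0.27 ± 0.79.

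**Figure D4:**
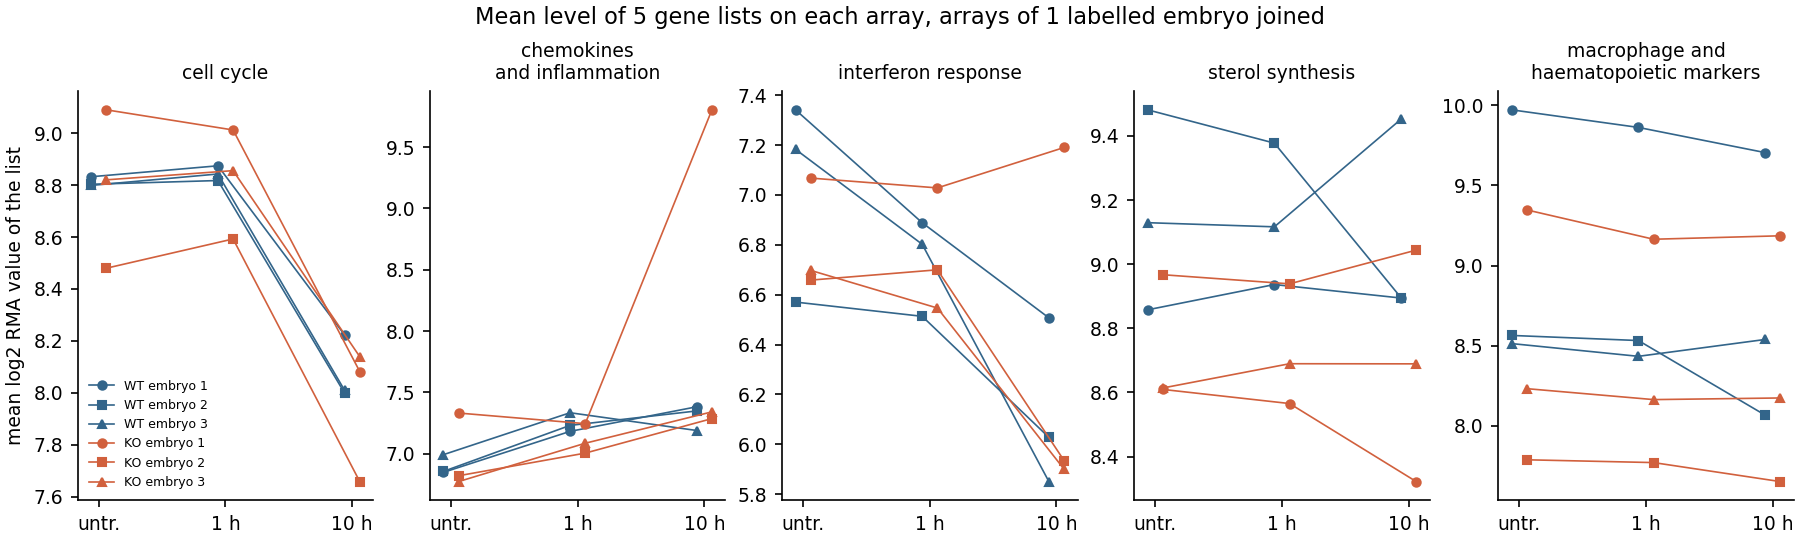
Mean log2 RMA value of 5 gene lists on each array (vertical) in untreated cells and after 1 h and 10 h of TGF-β1 (horizontal), with a line for the 3 arrays of each labelled embryo and a vertical axis of its own for each list. The chemokine and inflammation mean of knock-out embryo 1 reached 9.80 at 10 h, where the other 5 embryos lay between 7.19 and 7.38.

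Between the genotypes, 0 genes passed in limma after 1 h of TGF-β1 and 0 after 10 h. At 1 h Nnat, an imprinted proteolipid gene, was 1.13 ± 0.18 and Ppp1r3c 1.28 ± 0.21 (adjusted p = 0.120 each). They were followed by Sntb2 at 0.56 ± 0.09, Tinagl1 at 0.81 ± 0.15 and Angpt4 at 0.61 ± 0.12, and 846 genes had an unadjusted p under 0.05, where 684 would by chance among unpaired embryos (0 passed and 1559 had such a p with the replicate number as a block). The genotypes did not overlap in 14.3% of genes at 1 h and 7.60% at 10 h, where chance gives 10%. With array weights 9 genes passed at 1 h, all higher in cells labelled knock-out. At 10 h the p53 target gene Perp was 0.89 ± 0.16, the RNA demethylase gene Alkbh5 -0.53 ± 0.11, Nnat 0.88 ± 0.18, Mid1ip1 -0.46 ± 0.09 and Nnmt -0.60 ± 0.12, each with an adjusted p of 0.484. In this comparison 721 genes had an unadjusted p under 0.05, where 684 would by chance. Pdgfra was -0.69 ± 0.29 at 1 h and -0.83 ± 0.29 at 10 h (0.780 and 0.878). In the mean of the 3 conditions per embryo, which uses each embryo once, 0 genes passed in limma, 659 had an unadjusted p under 0.05, where 684 would by chance, and 10.4% did not overlap. Nnat was 0.93 ± 0.12, Chodl 0.84 ± 0.12, Plscr2 0.58 ± 0.08, Perp 0.72 ± 0.11 and Cth, an enzyme of cysteine synthesis, -0.42 ± 0.07, each with an adjusted p of 0.650. Pdgfra was -0.75 ± 0.23 (0.933). The 95% interval of that difference lay within 2-fold for 97.9% of the genes and within 1.5-fold for 93.0%.

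The sterol synthesis genes had a lower median in cells labelled knock-out in every condition. The conditions are cultures of the same embryos, so they repeat 1 comparison of embryos and do not replicate it. Their median was -0.45 at 1 h (camera adjusted p = 9.0e-09, adjusted p = 0.615 with an estimated correlation), -0.45 at 10 h (4.7e-09 and 0.603) and -0.44 in the embryo means (8.9e-14 and 0.580). Adjusted over the list alone 2, 4 and 4 of 17 members were lower, while 0 passed over all genes. In the embryo means these 4, named after their values were seen, were Stard4, a sterol transporter, at -0.46 ± 0.09, the feedback regulator gene Insig1 at -0.72 ± 0.18, Ebp at -0.21 ± 0.06 and Pmvk at -0.36 ± 0.10. The list kept its call without each embryo in turn in camera at the preset correlation. The list means of the 2 genotypes overlapped in each condition, at 10 h with 8.32 to 9.04 in labelled knock-out and 8.89 to 9.45 in wild type. At 1 h the replicate numbers were treated as pairing the genotypes, which is an assumption. There the list mean differed by -0.37, -0.44 and -0.43 within numbers 1, 2 and 3 (exact sign-flip p = 0.25, the smallest possible with 3 pairs). The exact permutation test of the list means over embryos gave p = 0.2 at 1 h, 0.3 at 10 h and 0.2 in the mean, where 0.1 is the smallest possible. The macrophage and haematopoietic markers were called lower at 1 h, with a median of -0.60 (0.0152 and 0.707), and in the embryo means, with -0.57 (0.0036 and 0.719), but not at 10 h, with -0.47 (0.133). The call was lost without wild-type embryo 1, knock-out embryo 2 or knock-out embryo 3, at 1 h (adjusted p = 0.744, 0.224 and 0.205) and in the embryo means (0.921, 0.248 and 0.0849). At 10 h the list was called without wild-type embryo 2 (0.0025) or knock-out embryo 1 (5.1e-05). Within numbers its mean differed at 1 h by -0.70, -0.76 and -0.27 (exact sign-flip p = 0.25). The exact permutation p was 0.4, 0.6 and 0.5.

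Other lists were called between the genotypes in treated cells, each with 0 members past limma. At 1 h the collagens (0.0484 and 0.707 as camera adjusted p without and with an estimated correlation), the matrix glycoproteins (0.0444 and 0.707), the contractile genes (0.0166 and 0.707) and the CDK inhibitors and p53 targets (0.0152 and 0.370) were higher. Their medians were 0.09, 0.02, 0.10 and 0.13. With the replicate number as a block in the list test, added after the data were seen, the collagens (0.0714) and matrix glycoproteins (0.120) were not called, the Hox genes were called higher (0.0116, against 0.0637 without it) and the chemokines lower (0.0105, against 0.418). At 10 h the immediate early genes (0.0322 and 0.902), the contractile genes (4.7e-04 and 0.603), the matrix proteases and inhibitors (0.0056 and 0.0799) and the chemokine and inflammation genes (4.7e-09 and 0.603) were higher and the cell cycle genes lower (0.0494 and 0.902). Their medians were 0.13, 0.06, 0.09, 0.75 and -0.15. In the embryo means 7 lists were higher, namely the contractile genes (0.0013 and 0.652), CDK inhibitors and p53 targets (0.0153 and 0.580), chemokines (0.0148 and 0.719), osteogenic genes (0.0203 and 0.580), Hox genes (0.0203 and 0.652), epithelial markers (0.0294 and 0.652) and neural markers (0.0485 and 0.580, and 0.0862 with the embryo numbers of the wild-type 10 h arrays 2 and 3 exchanged). Of these calls only that of the contractile genes in the embryo means was kept without each embryo in turn. At 1 h the collagens lost theirs without wild-type embryo 2 or knock-out embryo 1 or 3 (adjusted p = 0.517, 0.151 and 0.294), as did the matrix glycoproteins (0.660, 0.116 and 0.215). The contractile genes lost theirs without wild-type embryo 2 or knock-out embryo 2 or 3 (0.278, 0.181 and 0.199), and the CDK inhibitors without wild-type embryo 2 or knock-out embryo 3 (0.05 and 0.199). At 10 h the chemokine (0.812) and protease lists (0.0792) lost theirs without knock-out embryo 1 and the contractile genes without wild-type embryo 3 (0.140). The immediate early genes lost theirs without knock-out embryo 1 (0.812) and turned lower without wild-type embryo 3 (0.977). The cell cycle genes lost theirs without wild-type embryo 1 or 3 (0.924 and 0.0562) and turned higher without knock-out embryo 2 (0.504). In the other genotype comparisons this list was not called with all embryos, but was called in opposite directions by the embryo left out. Without knock-out embryo 1 it was lower in untreated cells, at 1 h and in the embryo means (camera adjusted p = 4.2e-05, 0.0069 and 3.1e-06). Without knock-out embryo 2 it was higher (7.0e-04, 0.0495 and 0.0061). In the embryo means the chemokines turned lower without knock-out embryo 1 (0.126). Without wild-type embryo 1 the CDK inhibitors (0.1), osteogenic genes (0.173), Hox genes (0.254), epithelial markers (0.327) and neural markers (0.236) lost their calls there. So did the CDK inhibitors (0.0955) and Hox genes (0.541) without knock-out embryo 2, the Hox genes (0.0832), epithelial (0.103) and neural markers (0.143) without knock-out embryo 3, and the neural markers without wild-type embryo 3 (0.0843) or knock-out embryo 1 (0.126).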

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

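In this part the test of the spread between embryos and the exchanged embryo numbers were chosen only after the result was seen. Of the 26 lists, 3 differed between the genotypes in the test of the difference between their 10 h responses. The median difference was 0.179 for the matrix proteases and inhibitors (camera adjusted p = 0.0098, adjusted p = 0.0929 with an estimated correlation), 0.365 for the interferon response genes (2.4e-04 and 0.737) and 0.584 for the chemokine and inflammation genes (6.9e-06 and 0.725). In limma 0 genes passed this interaction, with 305 at an unadjusted p under 0.05, and the chemokine members Cxcl5 at 2.04 ± 1.52, Saa3 at 1.66 ± 1.40 and Cxcl10 at 1.54 ± 1.27, named after their values were seen, were among those that did not.

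The chemokine mean changed from untreated to 10 h by 0.54, 0.49 and 0.20 in the 3 wild-type embryos and by 2.47, 0.47 and 0.57 in the 3 knock-out embryos, and the interferon mean by -0.83, -0.54 and -1.33 against 0.12, -0.72 and -0.80, so that in both lists knock-out embryo 1 stood apart. With the numbers of the wild-type 10 h arrays 2 and 3 exchanged, wild-type embryos 2 and 3 would give 0.33 and 0.36 for the chemokines and -0.72 and -1.15 for the interferon response. The exact permutation test of the embryos' mean responses had p up to 0.4 over the 3 lists (0.1 for the proteases, 0.3 for the chemokines), which decides nothing, because 3 against 3 cannot give a p under 0.1, and without knock-out embryo 1 or wild-type embryo 3 the count of lists past camera was 0. A spread between single embryos was expected to show as overlap of the genotypes in at least 1 of the 3 lists. The embryos overlapped for the chemokines (exact permutation p = 0.3) and the interferon response (0.4) and not for the proteases (0.1), so this was met. Such an overlap does not exclude an effect of the genotype. Which of the 2 could account for the lists therefore stays open. The 19 macrophage and haematopoietic markers had a median interaction of 0.128, with Csf1r at -0.03 ± 0.99, Ctss at -0.04 ± 0.83 and Cd14 at 0.58 ± 0.99. These errors ignore the embryo pairing and so include the differences between embryos. Within labelled embryos the mean of these markers changed from untreated to 10 h by -0.16 to -0.06 in knock-out. In wild type it changed by -0.50 to 0.03 (exact permutation p = 0.5). This argues against a rise of macrophages in the knock-out cultures by 10 h. Whether a smaller fall than in wild type could account for the lists stays open.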

How the results depend on the processing

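Tests added after the data were seen are embryo as a fixed block in the list tests, the replicate number in the list test, the numbers of the wild-type 10 h arrays 2 and 3 exchanged and both of these arrays left out. The counts of 0 for the genotype comparisons and interactions in limma stayed 0 under each alternative except for 9 genes at 1 h with array weights and, without knock-out embryo 2, 1 gene at 10 h. For wild type at 1 h, 134 probe sets passed when all were tested, 148 genes with array weights and 47 on the comparison's own arrays, against 80; for knock-out at 1 h, 113 probe sets and 39 genes on the own arrays, against 67. At 10 h 7296 probe sets passed in wild type and 7390 in knock-out, against 4614 and 4745 genes, since more units were tested, and 2516 genes in wild type without arrays 2 and 3, with 1 array left. The r of the 1 h responses was 0.972 and the slope 0.947 across genes called in wild type and the r 0.528 without the filter, against 0.586 and 0.745; at 10 h the r was 0.973 and 0.923 against 0.936. Except where the alternative's own construction shows it, the cause was not tested. Of 6805 pairs of a named gene result and an alternative 6499 kept their side of the threshold and direction, 285 lost it, 21 gained it and 0 reversed.

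Leaving out each embryo in turn gave 0 to 1 genes for knock-out against wild type at 10 h, 38 to 76 for wild type and 26 to 68 for knock-out at 1 h, and 3249 to 4585 and 3268 to 4894 at 10 h. The number of lists past camera ranged from 1 to 11 between the genotypes in untreated cells, 1 to 7 at 1 h, 3 to 10 at 10 h and 3 to 10 in the embryo means. For the responses it ranged from 4 to 8 (wild type) and 4 to 7 (knock-out) at 1 h, 6 to 9 and 8 to 11 at 10 h, and for the interactions from 0 to 3 at 1 h and 0 to 6 at 10 h. The r of the responses ranged from 0.475 to 0.617 at 1 h and 0.892 to 0.925 at 10 h, and the slope from 0.561 to 0.889 and 0.971 to 1.08. With an estimated correlation 1 list (SMAD feedback and early targets) passed at 1 h in each genotype, and 0 lists passed in the 10 h responses, the genotype comparisons in untreated cells, at 1 h, at 10 h and in the embryo means, and the 10 h interaction.

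With embryo as a replicate block, fixed or random, 113 and 114 genes passed in wild type at 1 h, 101 and 95 in knock-out at 1 h, 5492 and 5446 in wild type at 10 h (6007 with the numbers of arrays 2 and 3 exchanged) and 5509 and 5413 in knock-out at 10 h, and 0 in both interactions. In the list tests the fixed block gave 3 lists for the 1 h and 5 for the 10 h interaction, the same with the exchanged numbers, and with an estimated correlation 1 list at 1 h in each genotype, 0 at 10 h in each and 0 for both interactions. The replicate number as a block between the genotypes left their counts at 0, and in the list test at 1 h it gave 0 lists with an estimated correlation. With the exchanged numbers the embryo means gave 0 genes and 8 lists, against 9. Apart from the list calls named in the report the block changed no call of a list; which single genes it changed is given as counts only. The 4515 genes too dim to test were not compared, and among tested genes of any brightness a change of 0.5 was recovered in 35.8% of simulated genes for knock-out against wild type in untreated cells.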

Other observations

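Dbp, a clock output gene, had the largest fall at 10 h in both genotypes, and other clock genes, which were no fixed list and were not tested as one, were looked up afterwards. In wild type Dbp fell by 4.25 ± 0.10, Tef by 1.03 ± 0.10, Nr1d2 by 1.48 ± 0.11, Per3 by 1.35 ± 0.13 and Nr1d1 by 0.57 ± 0.17. Arntl, which encodes the activator BMAL1, rose by 2.16 ± 0.12, Nfil3 by 1.68 ± 0.12, Cry1 by 1.51 ± 0.13 and Clock by 0.44 ± 0.10. In knock-out Arntl rose by 2.18 ± 0.12 and Nr1d2 fell by 1.59 ± 0.11. In the 10 h interaction 0 of these genes passed in limma. At 1 h Per2 was at 1.03 ± 0.21 in wild type and 0.83 ± 0.21 in knock-out (adjusted p = 0.0273 and 0.157), and Nfil3 at 0.42 ± 0.12 and 0.75 ± 0.12 (0.224 and 0.0041).

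In this part the tests of the clock genes and of both wild-type 10 h arrays were chosen only after the results were seen. A first set of 10 clock genes held output genes such as Dbp together with the Per and Nr1d genes, which encode parts of the clock itself. In this set 5 were lower at 10 h in each genotype and 1 was higher in wild type, with medians of -0.428 in wild type and -0.646 in knock-out. Of 5 others, which include the repressor genes Nfil3 and Cry1, 4 were higher in each, with medians of 1.51 and 1.67. Arntl, Nfil3, Cry1 and Clock rose in both genotypes, with 1.51 as the lower median of their set. A general loss of transcription factor transcripts was expected to lower the medians of both sets, which was not seen. These genes were looked up afterwards, so this speaks only for the clock transcripts named, relative to other genes. A loss common to all transcripts could not be seen here, because RMA normalizes the arrays to each other. No untreated culture kept for 10 h was analysed here. Whether TGF-β1 or 10 h in medium with an albumin supplement lowered the first set (median -0.428 in wild type) therefore cannot be told apart. The same holds for other 10 h changes.

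The wild-type 10 h arrays of embryos 2 and 3 deviated from the earlier arrays of their own numbers and correlated with those of the other number, array 2 with embryo 3 at 0.382 and 0.372 (untreated and 1 h) and array 3 with embryo 2 at 0.439 and 0.359. Over the 200 genes with the largest difference between embryos 2 and 3 before, the difference at 10 h had an r of -0.744 across genes. The other 5 pairs of embryos of a genotype had an r between 0.432 and 0.737. A difference in RNA quality was expected to put 1 of the 2 arrays outside the actin 3' minus 5' range of the other 16 (0.07 to 0.54). This was not met, as 0 lay outside. The Gapdh controls, not part of that bound, put 1 array narrowly outside, at -0.307 (-0.291 to 0.03). That each array matched the earlier arrays of the other number argues against RNA quality as the whole account. A part played by it was not excluded. The values are consistent with exchanged embryo numbers on these 2 arrays, which would leave the group means as they are but not the embryo means, the embryo responses, the block or the results without wild-type embryo 2 or 3. Another difference between these cultures stays open, and no biological explanation was tested.

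As a hypothesis, a targeted locus could carry flanking differences in expression between the genotypes. The 100 tested genes nearest to Nfic on chromosome 10 had a mean absolute moderated t of 0.978, against a median of 0.890 over 11604 windows, at percentile 84.3, and 8 of them had an unadjusted p under 0.05 and 0 an adjusted one, which decides nothing about the labels. As another hypothesis, genes that rise with TGF-β1 could already be higher in untreated knock-out cells. The correlation across genes of the genotype difference in untreated cells with the mean change from 1 h to 10 h was 0.0172 (Spearman 0.0223), 8 of 10 splits of the embryos gave an r at least as far from 0 (exact permutation p = 0.8, r from -0.196 to 0.244), and the hypothesis was not borne out for that part of the response.

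The 6 samples of a comparison can be split into 3 against 3 in 10 ways, too few for a share under 0.05. For TGF-β1 against untreated cells the real split called 80 and 4614 genes in wild type and 67 and 4745 in knock-out, the highest other split called 0, and 1 of 10 splits, the real one, called as many. For knock-out against wild type in untreated cells, at 1 h and in the embryo means, and for both interactions, the real split called 0 genes, the highest other 0, and 10 of 10 splits called at least as many. A real count of 0 fixes this share in advance, so it carries no information, here and at 10 h. At 10 h the real split called 0 genes and 10 of 10 splits at least as many. By the labelled numbers, wild-type embryos 1 and 3 with knock-out embryo 2 against the other 3 called 32. Wild-type embryos 1 and 2 with knock-out embryo 1 against the rest called 4. These counts point to a structure of the samples that does not follow the genotype. The numbers of wild-type arrays 2 and 3 may be exchanged there.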
